A study of Mus musculus with 6 samples.

How the data were processed

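RNA from BV2 cells was labelled with Cy5 as cDNA and hybridised to single-colour Phalanx mouse OneArray microarrays, per the labels' protocols. The deposited values are spot intensity on a linear scale, whole numbers from −21 to 65489, and are background-subtracted, since some lie below 0. The submitters' processing notes name RMA, a method that gives values on a log scale with equal distributions on every array. The deposited intensity values are linear and their medians differ between arrays (125, 137, 143, 170, 147 and 129 units for control 1 and 2, lower dose 1 and 2 and higher dose 1 and 2), so they were treated as not normalized between arrays. Scanner, background method and spot averaging are not given in the sources used here, and neither are detection flags, slide or scan labels.

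The plan written before the data were examined took log2 of the values as deposited, after a floor of 1 if they were linear, with no normalization between arrays, and listed quantile normalization as an alternative. The analysis departs from it: because the array medians differed, the arrays were quantile-normalized, a decision made after the values had been inspected and before any test was run. Values under 1 were then set to 1 and log2 was taken. The planned fit is kept as an alternative, and its counts are given beside the results. Between 196 and 315 probes per array lay under 1 and 10 to 39 were at or above 65000 units, near the 16-bit ceiling. Values at either end compress or inflate a fold change.

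Groups came from the sample titles: control, lower dose and higher dose, 2 arrays each. Titles and treatment protocol state 20 and 80 µM, and characteristics state 80 and 250 µM, for 1 h. This conflict was not resolved, and only the order of the doses is used. All 6 arrays were fitted together in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, 1 mean per group, 3 residual degrees of freedom, two-sided tests, Benjamini-Hochberg adjustment, threshold 0.05). Comparisons were each dose against control, the doses against each other, and both doses averaged against control. Errors are standard errors of the log2 change from this fit. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

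Probe names came from the array's platform annotation, which is old and gives 1 symbol for 20377 of 26423 probes, several for none, and leaves 6046 unnamed here. Symbols were updated by exact match (18213) or a unique synonym (2126) in a RefSeq table of assembly GRCm38.p6, and 38 were kept as given. The files name no genome build, so no coordinates are given, and the table's gene spans serve only as a property of genes. The probe brightest on average stood for a gene, and other probes of a named gene are given where they disagree. Nos2, Adora2a, Adora2b and Gapdh, meant to be reported in any case, are not named among the probes used here.

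In the same plan, 29 gene lists were fixed, of pathways and cell type markers. Lists with at least 5 measured genes, 28 of them, were tested with camera against all other named genes at a preset inter-gene correlation of 0.01, and again with an estimated one. For lists called at the higher dose, estimates ranged from −0.024 (oxidative phosphorylation) to 0.068 (glycolysis), on both sides of the preset. A larger p with an estimated correlation is therefore not by itself a sign of correlation between genes. The remaining list had 4 of 9 genes measured and was not tested. The rule for named genes, also fixed then, took the 8 largest changes in each direction past the threshold with separate arrays and a mean above the median probe (5 per direction between the doses), filled by smallest p where fewer passed, 2 members with the smallest p of each list, and a fixed set of inflammatory, immediate early, purine and reference genes.

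The fit was tested on simulated data built on the lower-dose comparison. In a single run, 200 probes above the median intensity were changed, 100 by each size, with each probe's own residual spread. With all 26423 probes, 0% of changes of log2 size 1 and 54% of size 2 were recovered. These shares hold for that number of changed probes, on which the adjustment depends. With the 13211 brighter probes, 44% and 92% were recovered, counted without regard to sign. Calls among unchanged probes were counted only in the fit to all 26423 probes and numbered 0. Alternatives were no normalization, scaling to equal medians, filters on dim probes, log2(value + 16), the replicate number as a block, a trended prior, array weights, only the groups compared, other thresholds, leaving out each array, the mean of all probes of a gene, an estimated correlation, and removal of each array's lowess trend with log2 gene span. With 2 arrays per group, other splits of the samples were not counted.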

Results

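Gene expression was measured in BV2 cells, an immortalised line of mouse microglia, the resident macrophages of the brain, after 1 h with or without adenine, a purine base that cells salvage into nucleotides. The data were 6 single-colour arrays: 2 of untreated control cells, 2 of cells given a lower adenine dose and 2 of cells given a higher dose. The labels disagree on the doses. Titles and treatment protocol give 20 and 80 µM, and the sample characteristics give 80 and 250 µM. Both rank the groups alike, so they are called lower and higher dose here. Each array carried 26423 probes with background-subtracted intensities, whose medians as deposited ranged from 125 to 170 units. With 2 arrays per group, the number of arrays limits the precision of every value. The study's design text describes separate cultures for control and treated cells. The sample titles do not say whether the 2 arrays of a group came from separate cultures. If they did not, the errors and p-values given here would not measure variation between cultures.

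The 2 higher-dose arrays differed from the other 4. Over probes above the median intensity, their log2 values correlated with each other at r = 0.9894 and with the other arrays at 0.9287 to 0.9406, while the control and lower-dose arrays correlated among themselves at 0.9782 to 0.9858. The first principal component held 70.93% of the variance and placed the higher-dose arrays at 52.51 and 50.94 and the others between −28.35 and −23.17. The second, with 11.25%, set lower-dose replicate 2 (−29.33) apart from lower-dose replicate 1 (6.601).

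The first comparison asked which transcripts differed after 1 h of the lower dose. Foxj1, a transcription factor known for its part in forming motile cilia, rose 17.7-fold, from a mean normalized intensity of 81.4 to 1440 (log2 change 4.14 ± 0.21, SE, n = 2 per group, adjusted p = 0.0444). Only 2 other probes of the 26423 passed, and they lie outside the rule for named genes and were named after their values were seen. Values below 1 were set to 1, so no fold is given for them. Ankrd61 read −3 and −1 units in the controls and 81 and 66 units at the lower dose (adjusted p = 0.0444), and Rtl3 read 121 and 134 units in the controls and 2 and 0 units at the lower dose (adjusted p = 0.0444). At the higher dose Foxj1 and Ankrd61 were also raised (adjusted p = 0.00532 and 0.00973), whereas Rtl3 read 95 and 104 units (adjusted p = 0.395). Genes that came next by p without passing included Slfn2 (log2 −0.85 ± 0.16), the chemokine receptor Cxcr4 (−0.82 ± 0.16) and Tfeb (−0.76 ± 0.14), all at adjusted p = 0.764. At an unadjusted p under 0.05, 1681 probes differed. The call for Foxj1 was lost in each of the 6 fits without 1 array (highest adjusted p over its alternatives 0.337), while its log2 change stayed between 3.90 and 4.41, and the count of 3 probes became 9 without control replicate 1, 1 without control replicate 2 and 0 when any 1 of the 4 treated arrays was left out. The planned fit to values as deposited also called 3, and the count was 0 after scaling arrays to equal medians, with array weights, or with only the control and lower-dose arrays in the fit.

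Among the gene lists fixed in advance, interferon-stimulated genes shifted down at the lower dose (median log2 change −0.30 over 28 genes, camera adjusted p = 0.000796), as did immediate early genes (−0.17 over 30 genes, adjusted p = 0.00168), whose median on values as deposited was 0.01, or −0.21 relative to the median of all probes. Both had adjusted p = 0.39 with an estimated correlation between genes. No member of either list passed alone, with 0 genes past the threshold also when adjusted over the list alone. Of the interferon-stimulated genes, 22 of 28 had negative values, including Irf9 (−0.51 ± 0.14) and Oas2 (−0.51 ± 0.15), both at adjusted p = 0.764. Of the immediate early genes, Klf2 (−0.73 ± 0.16) and Nr4a1 (−0.65 ± 0.18) had the smallest p, both at adjusted p = 0.764, and Fos stood at −0.47 ± 0.17. Endothelial markers shifted up (0.29 over 8 genes, adjusted p = 0.047, and adjusted p = 0.503 with an estimated correlation), a call lost under 8 of 14 alternatives. Array means of the interferon-stimulated genes, relative to the control mean, were −0.449 and −0.018 at the lower dose and 0.15 and −0.15 in the controls, so the groups overlapped. This call was lost without control replicate 2 or lower-dose replicate 1 (highest adjusted p = 0.166), where the list median was −0.27 and −0.24. The immediate early gene call was lost without the same arrays (highest adjusted p = 0.185), although the array means of this list at the lower dose, −0.263 and −0.193, lay below both controls (−0.041 and 0.041).

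**Figure D1:**
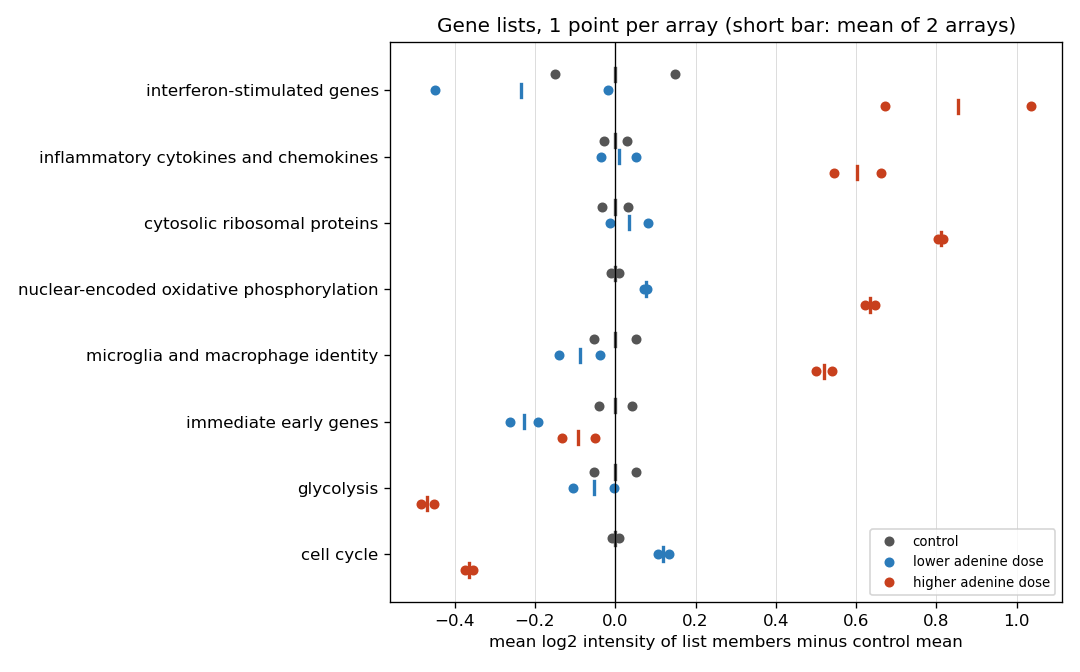
Mean log2 intensity of the members of 8 gene lists on each of the 6 arrays, minus the control mean, with 1 point per array and a short bar at the mean of each group of 2. The higher-dose arrays lie at 0.673 and 1.037 for interferon-stimulated genes and at −0.355 and −0.373 for cell cycle genes.

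The second comparison asked the same of the higher dose. Of 26423 probes, 1466 rose and 1337 fell at an adjusted p of 0.05. They stood for 1131 genes that rose and 956 that fell among 17742 named genes. The planned fit to values as deposited called 2138, 1195 of them higher. The balance turned with equal medians (1378 higher and 1766 lower) and with log2(value + 16) (2270 higher and 2494 lower). Among genes above the median intensity whose arrays lay apart, the largest rises were Foxj1 (41.6-fold, log2 5.38 ± 0.21, adjusted p = 0.00532), the membrane protein gene Ms4a7 (13-fold, 3.70 ± 0.21, adjusted p = 0.0118), the interferon-induced Ifi27l2a (8.05-fold, 3.01 ± 0.20) and Isg15 (7.87-fold, 2.98 ± 0.17), which encodes a ubiquitin-like modifier, the apolipoprotein gene Apoc1 (7.65-fold, 2.94 ± 0.18), C1qa (6.91-fold, 2.79 ± 0.19) and Cfp (6.89-fold, 2.78 ± 0.15) of the complement system, and the protease inhibitor gene Slpi (6.53-fold, 2.71 ± 0.24). The largest falls by the same rule included Ammecr1 (8.04-fold lower, log2 −3.01 ± 0.21), the sterol carrier Stard4 (6.41-fold lower, −2.68 ± 0.16), the corepressor Rcor1 (5.61-fold lower, −2.49 ± 0.22), the ubiquitin ligase Cbl (5.07-fold lower, −2.34 ± 0.18), Dnajb14 (−2.26 ± 0.24) and Tob1 (−2.26 ± 0.20). Adjusted p for these 6 lay between 0.0119 and 0.0199. Larger falls of Mbnl2 and Eid1 rested on 1 of 2 probes. Mbnl2, a splicing regulator, fell 11.9-fold by its brighter probe (−3.58 ± 0.16, adjusted p = 0.00799), and its other probe read −0.47 (adjusted p = 0.259). The brighter Eid1 probe read −2 and 8 units at the higher dose against 4872 to 5920 on the other arrays (adjusted p = 0.0185), and the second Eid1 probe read 0.14 (adjusted p = 0.786).

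The count of 2803 probes was 14 and 8 without control replicate 1 and 2, 6 and 30 without higher-dose replicate 1 and 2, and 1589 and 1583 without lower-dose replicate 1 and 2, fits that leave 2 residual degrees of freedom in place of 3. It was 1584 with only the control and higher-dose arrays in the fit and 5524 when only probes above the median intensity were tested.

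**Figure D2:**
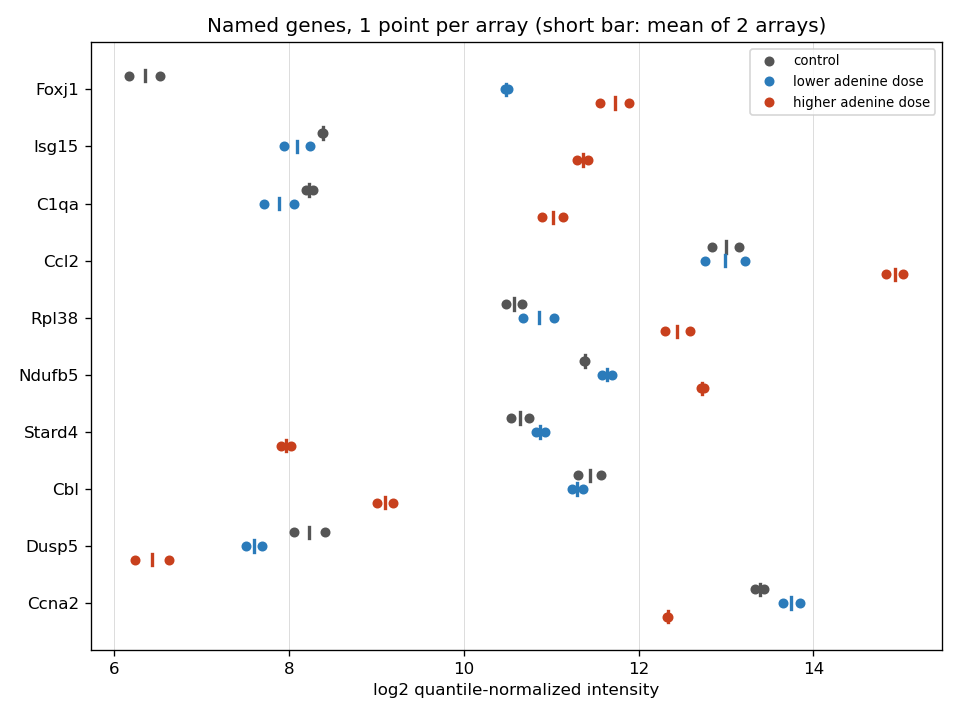
Log2 quantile-normalized intensity of 10 named genes on each array, with 1 point per array and a short bar at the mean of each group of 2. Foxj1 was raised at both doses, whereas Isg15, C1qa and Ccl2 lay apart from the controls at the higher dose, with log2 changes of 2.98, 2.79 and 1.93.

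At the higher dose, interferon-stimulated genes and cytokines had positive list medians. Of 28 interferon-stimulated genes, 11 rose and 0 fell (16 and 0 adjusted over the list alone). Their median log2 change was 0.73 (camera adjusted p = 4.46e-07, and adjusted p = 0.132 with an estimated correlation). That estimate, −0.0088, was below the preset of 0.01, so correlation between these genes does not account for the larger p. The larger p rests instead on the 3 residual degrees of freedom of the arrays. Isg15 rose as given above, and the chemokine Cxcl10 rose 3.72-fold (1.89 ± 0.23, adjusted p = 0.0204). Of 29 inflammatory cytokines and chemokines, 9 rose and 2 fell (13 and 3 adjusted over the list alone), with a median of 0.47 (adjusted p = 0.003, and adjusted p = 0.257 with an estimated correlation), and of 0.30 after the trend with gene span was removed (adjusted p = 0.0153). The monocyte chemoattractants Ccl7 (5.76-fold, 2.53 ± 0.21, adjusted p = 0.0185) and Ccl2 (3.82-fold, 1.93 ± 0.23, adjusted p = 0.0204) and the chemokine Ccl9 (4.12-fold, 2.04 ± 0.23, adjusted p = 0.0204) rose. Tnf (0.47 ± 0.30, adjusted p = 0.364), Il1b (0.52 ± 0.15, adjusted p = 0.0894), Il6 (1.19 ± 0.33, adjusted p = 0.082) and Ptgs2 (−0.76 ± 0.22, adjusted p = 0.0967) did not pass, although Il6 and Ptgs2 did with log2(value + 16) (adjusted p = 0.03 and 0.0418). Of 22 microglia and macrophage identity genes, 7 rose and 1 fell (8 and 1 adjusted over the list alone), without a shift of the list past the threshold (median 0.26, adjusted p = 0.0653). The complement genes C1qa and C1qc (2.54 ± 0.18, adjusted p = 0.0163) were among them. The antigen presentation list did not pass (median 0.28, adjusted p = 0.194), with 5 of 18 genes higher and 1 lower, also adjusted over the list alone, and the immunoproteasome subunits Psmb8 (1.54 ± 0.19, adjusted p = 0.0204) and Psmb9 (1.95 ± 0.25, adjusted p = 0.0212) rose. The feedback inhibitor of NF-κB, Nfkbia, rose 1.99-fold (0.99 ± 0.18, adjusted p = 0.0332), while 2 genes rose and 2 fell of the 21 in its list of NF-κB feedback genes and early targets (median 0.19, adjusted p = 0.746). Of 34 Toll-like receptor signalling genes, 0 rose and 4 fell (median −0.26, adjusted p = 0.23), including Tab2 (−0.99 ± 0.16, adjusted p = 0.028) and Mapk8 (−0.94 ± 0.16, adjusted p = 0.03). Of 21 alternative activation and anti-inflammatory genes, 3 rose and 0 fell (median 0.22, adjusted p = 0.194), including Arg1 (1.17 ± 0.19, adjusted p = 0.0276) and Tgfb1 (1.17 ± 0.22, adjusted p = 0.0386). For these 3 lists, the counts adjusted over the list alone were equal.

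The lists of ribosomal proteins and oxidative phosphorylation also had positive medians. Of 21 cytosolic ribosomal protein genes measured of 42 listed, 11 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 change of 1.10 (camera adjusted p = 5.69e-06, and adjusted p = 0.257 with an estimated correlation), among them Rpl38 (3.66-fold, 1.87 ± 0.21, adjusted p = 0.0199) and Rpl23 (2.75-fold, 1.46 ± 0.17, adjusted p = 0.0204). Of 32 nuclear-encoded genes of oxidative phosphorylation, 15 rose and 2 fell (21 and 3 adjusted over the list alone), with a median of 0.89 (adjusted p = 2.68e-06, and adjusted p = 0.132 with an estimated correlation), among them the complex I subunit Ndufb5 (2.54-fold, 1.34 ± 0.14) and the ATP synthase subunit Atp5o (2.61-fold, 1.38 ± 0.16), both at adjusted p = 0.0199. These genes are short, with median spans of 3.81 and 9.07 kb in the GRCm38.p6 annotation, and the higher-dose change followed gene span. Across 10269 genes, which are not independent replicates, the change correlated with span at Spearman's rho = −0.326, against 0.0607 for the lower dose and −0.0447 to 0.0166 between replicates. After this trend was removed from each array, the medians were 0.93 and 0.79 (adjusted p = 0.000216 and 9.08e-06).

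**Figure D3:**
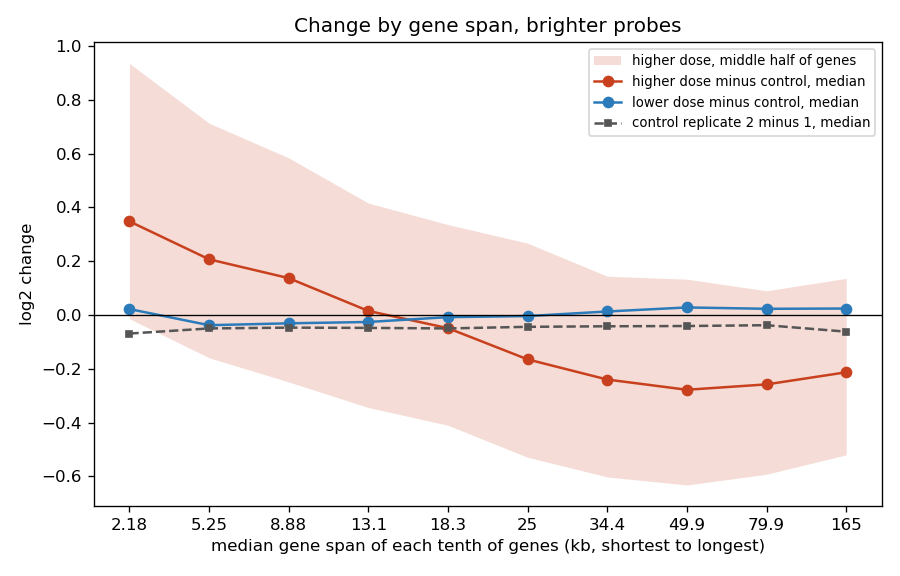
Median log2 change against the median span, in kb, of 10 equal groups of 10269 genes ordered by span, for the higher and the lower dose minus control and for control replicate 2 minus replicate 1. The shaded band covers the 25th to 75th percentile of genes at the higher dose, whose median goes from 0.348 in the group of shortest genes to −0.213 in that of the longest.

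The cell cycle and glycolysis lists had negative medians at the higher dose. Of 31 cell cycle genes, 11 fell and 1 rose (16 and 5 adjusted over the list alone), with a median log2 change of −0.50 (camera adjusted p = 0.0138, and adjusted p = 0.362 with an estimated correlation). The cyclin-dependent kinase gene Cdk2 fell 2.35-fold (−1.23 ± 0.16, adjusted p = 0.0216) and its cyclin partner Ccna2 fell 2.07-fold (−1.05 ± 0.16, adjusted p = 0.0252). Of 15 glycolysis genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of −0.28 (adjusted p = 0.0214, and adjusted p = 0.438 with an estimated correlation), among them hexokinase Hk2 (2.25-fold lower, −1.17 ± 0.18, adjusted p = 0.026) and phosphofructokinase Pfkm (2.26-fold lower, −1.17 ± 0.20, adjusted p = 0.0304). Both list calls were lost on values as deposited and after scaling arrays to equal medians, with medians of −0.51 and −0.58 for cell cycle (adjusted p up to 0.0951) and of −0.13 and −0.20 for glycolysis. The glycolysis call was also lost among probes above the median intensity and without control replicate 1 or higher-dose replicate 1 (highest adjusted p = 0.135).

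Among other lists, 22 did not pass at the higher dose (adjusted p 0.0653 to 0.93), although single members changed. In purine metabolism and salvage, 2 genes rose and 6 fell of 33 (4 and 8 adjusted over the list alone, median −0.27, adjusted p = 0.302). Aprt, the enzyme that converts adenine to AMP, rose 1.96-fold (0.97 ± 0.19, adjusted p = 0.0392). The adenylosuccinate synthase gene Adss (−1.30 ± 0.16, adjusted p = 0.0204) and the purine transporter gene Slc43a3 (−1.16 ± 0.19, adjusted p = 0.028) fell. Hprt, which salvages hypoxanthine and guanine, stood at 0.20 ± 0.17 (adjusted p = 0.501), and at 0.54 on values as deposited and 0.46 with equal medians. Of 9 purinergic and adenosine receptors measured of 23 listed, 0 passed in limma, also adjusted over the list alone (median 0.32, adjusted p = 0.443). Of 30 immediate early genes, 4 fell and 1 rose, also adjusted over the list alone (median −0.06, adjusted p = 0.767). The phosphatase gene Dusp5 (−1.80 ± 0.22, adjusted p = 0.0204) and the nuclear receptor Nr4a1 (−1.19 ± 0.18, adjusted p = 0.0261) fell, while Fos (−0.44 ± 0.17, adjusted p = 0.167, and −0.16 on values as deposited), Egr1 (0.60 ± 0.23, adjusted p = 0.158) and Jun (0.03 ± 0.21, adjusted p = 0.945, and −0.08 on values as deposited) did not pass. Of 21 genes of the integrated stress and unfolded protein responses, 1 rose and 2 fell (1 and 4 adjusted over the list alone) and 15 had negative values. Their median was −0.52 (camera adjusted p = 0.11, and adjusted p = 0.438 with an estimated correlation). It was −0.43 after the trend with gene span was removed (adjusted p = 0.0444), −0.27 on values as deposited (adjusted p = 0.297) and −0.35 with equal medians (adjusted p = 0.32). Among them, Ddit3 rose (1.06 ± 0.15, adjusted p = 0.0231) and Xbp1 fell (−0.87 ± 0.16, adjusted p = 0.0356). Over 15 alternatives, the log2 change was 0.95 to 1.09 for Ddit3 and −0.95 to −0.51 for Xbp1. The cholesterol synthesis enzyme Sqle fell (−1.26 ± 0.15, adjusted p = 0.0204). Actb, at or near the scanner's ceiling on some arrays, stood at −0.22 ± 0.14 (adjusted p = 0.373), and at −0.01 on values as deposited. Markers of astrocytes, neurons, oligodendrocytes, fibroblasts, endothelium and lymphocytes held 0 genes past the threshold at the higher dose, with list medians from −0.27 to 0.22 and adjusted p from 0.314 to 0.849.

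The third comparison set the doses against each other. Relative to the lower dose, 1792 probes were higher and 1837 lower at the higher dose. By the same rule, the largest rises were Ms4a7 (11.7-fold, log2 3.55 ± 0.21, adjusted p = 0.0143), Isg15 (9.66-fold, 3.27 ± 0.17, adjusted p = 0.013), C1qa (8.76-fold, 3.13 ± 0.19), C1qb (8.37-fold, 3.07 ± 0.25) and C1qc (7.4-fold, 2.89 ± 0.18), and the largest falls beside the single Eid1 probe were Mbnl2 (12.8-fold lower, −3.67 ± 0.16, by its brighter probe), Stard4 (7.51-fold lower, −2.91 ± 0.16), Ammecr1 (7.19-fold lower, −2.85 ± 0.21) and Rcor1 (6.16-fold lower, −2.62 ± 0.22). Interferon-stimulated genes were higher as a list (median 0.99, adjusted p = 2.15e-09, and adjusted p = 0.147 with an estimated correlation), with 14 genes higher and 0 lower of 28. Ribosomal protein genes (median 1.00, adjusted p = 1.77e-05), oxidative phosphorylation (0.79, adjusted p = 1.13e-05) and cytokines and chemokines (0.51, adjusted p = 0.00206) were higher and cell cycle genes lower (−0.63, adjusted p = 0.00121), with adjusted p from 0.154 to 0.231 with an estimated correlation. The count of 3629 was 7 with only the 4 arrays of the 2 doses in the fit. It was 7 without either control array, 9 without either lower-dose array, and 6 and 26 without higher-dose replicate 1 and 2. In the planned fit to values as deposited, whose median change between the doses was −0.247, 4092 probes were called, 1127 higher and 2965 lower.

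Averaged over both doses, 5 probes differed from control, 3 of them higher and 2 lower, and 4283 at an unadjusted p under 0.05. The count was 11 and 2 without control replicate 1 and 2, 0 and 3 without lower-dose replicate 1 and 2, 0 without either higher-dose array, and 7 in the planned fit to values as deposited. The 5 were named after their values were seen. Foxj1 (log2 4.76 ± 0.18, adjusted p = 0.00793) and Ankrd61 (adjusted p = 0.0135, against controls set to the floor of 1) were raised at each dose, whereas the probes for Pacs1 (421 and 410 units), Tti1 (−6 and −8 units) and an unnamed transcript (−1 and −1 units) departed at the higher dose, against 1 and 0, 1552 and 1464, and 138 and 132 units in the controls. The changes at the 2 doses correlated across 26423 probes, which are not independent replicates, at r = 0.295. Simulated unchanged groups with shared simulated controls gave a mean of 0.498. These 2 correlations are not directly comparable, since the observed changes varied more at the higher dose (variance 0.505) than at the lower (0.201). The covariance of the changes was 0.0942 against a simulated 0.0967 (0.0851 to 0.109), a difference of −0.00251. The 2 rises shared by both doses compare with 0.11 for independent lists, and part of any excess may come from the shared controls, which are too few to split.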

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

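In this part, the tests of scaling, of a batch and of a single array in the higher-dose part of the interferon pattern were chosen only after the result was seen. Removal of the gene span trend was not planned either and was chosen after seeing the data. The outcomes that would count for or against it were written before its results were seen.

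A direct test of the difference between the doses marked 3629 probes, and the higher-dose arrays stood apart from the other 4. The tables argue against a constant factor per array as the source. The count against control was 2138 on values as deposited and 3144 with equal medians, against 2803. With log2(value + 16), which keeps the quantile normalization and changes only the offset, it was 4764. These settings do not test every array difference that varies with intensity. The average trend with gene span does not account for most calls, since 2680 named probes were called after it was removed, against 3077 before. That trend was small beside the spread among genes of like span. In the group of shortest genes the median was 0.348, and the 25th to 75th percentile ran from −0.014 to 0.935. Removal could therefore end few calls, and it does not test a cause that span tracks only in part. An unrecorded array or culture batch cannot be told apart from the dose, because 0 labels give a slide, scan, date or batch and all higher-dose arrays belong to 1 group. An effect of the dose stays open for the same reason.

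The interferon-stimulated genes were marked because their median log2 change was −0.30 at the lower and 0.73 at the higher dose, and the difference of 0.99 was tested directly (camera adjusted p = 2.15e-09, and adjusted p = 0.147 with an estimated correlation). The average trend with gene span does not account for the difference, since the median was 0.87 after the trend was removed against 0.99 before. The list's median span was 13.5 kb, and the group of genes with a median span of 13.1 kb changed by 0.015 at the higher dose. Removal could therefore change little, and it does not test a cause that span tracks only in part. Resampling the genes of the list gave a bootstrap 95% interval of 0.56 to 1.39 after removal. The tables argue against a single array for the higher-dose part. There the lowest median without 1 array was 0.6, and the array means of 0.673 and 1.037 lay above both controls. For the lower-dose part the median and the mean point apart, so a single array stays open. Medians kept their signs in 6 of 6 fits, the outcome written beforehand as going against a single array. The bootstrap intervals and array means used here were not part of that rule. Without lower-dose replicate 1 the median was −0.24 (bootstrap 95% interval over genes −0.42 to −0.04). The list mean of lower-dose replicate 2 (−0.018), however, lay between the controls (0.15 and −0.15). Both intervals measure spread among genes on these arrays and not variation between arrays or cultures. The camera p-value at the preset correlation likewise does not reflect the small number of arrays. Dose and an unrecorded batch both remain open.

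Cell cycle genes differed between the doses by a median of −0.63 (camera adjusted p = 0.00121, and adjusted p = 0.231 with an estimated correlation). Their median was 0.16 at the lower dose (adjusted p = 0.0562, and 0.503 with an estimated correlation), and 0.18 after the span trend was removed (adjusted p = 0.0298 at the preset correlation). At the higher dose it was −0.50 (adjusted p = 0.0138, and 0.362 with an estimated correlation). Inflammatory cytokines and chemokines differed by 0.51 (adjusted p = 0.00206, and adjusted p = 0.231 with an estimated correlation), with medians of −0.13 (adjusted p = 0.334, mean 0.01) and 0.47 (adjusted p = 0.003, and 0.257 with an estimated correlation).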

How the results depend on the processing

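Alternatives chosen after seeing the data were log2(value + 16) for probe counts and named genes, removal of the span trend, and, for every result, values as deposited, which had been the planned fit. Main counts of changed probes were 3 (lower dose), 2803 (higher dose), 3629 (between doses) and 5 (both averaged), in that order below. The planned fit gave 3, 2138, 4092 and 7. Fits without 1 array gave 0 to 9, 6 to 1589, 6 to 26 and 0 to 11, with a lone array assumed to vary like the other groups. Testing probes above the median gave 1, 5524, 6163 and 1593, and above the lower quartile 1, 4883, 5730 and 506, where fewer dim probes enter the prior. A trended prior gave 5000, 5762 and 721 for the last 3, and log2(value + 16) gave 4764, 5645 and 483. With only the groups compared, the first 3 were 0, 1584 and 7, with fewer arrays for the spread. Scaling to equal medians and array weights each left 0 at the lower dose, and array weights gave 9 for both averaged. An adjusted p of 0.1 gave 5262, 6425 and 14 for the last 3, a 2-fold minimum gave 2216 between doses, and an unadjusted p of 0.05 with a 2-fold change gave 424 at the lower dose and 581 for both averaged. For both averaged, calls split 3 higher and 2 lower, against 3 and 4 as deposited, 2 and 5 with equal medians, and 355 and 128 with log2(value + 16). Whether the replicate numbers pair the arrays is not stated, and 2 arrays per group cannot settle it. Among probes above the median, deviations correlated at 0.0326 (control and lower dose), 0.313 (control and higher dose) and −0.226 (the 2 doses). Over all probes the values were 0.0679, 0.0542 and −0.0464. The replicate block gave 0, 11, 1395 and 0. As deposited, the median change of all probes was 0.222 at the lower dose, −0.247 between doses and 0.103 for both averaged, so directions there are relative to it. The cause of the other changes was not tested.

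Shifted lists numbered 3 at the lower and 6 at the higher dose, 2 and 5 in the planned fit, 0 and 0 with an estimated correlation, and 0 to 3 and 5 to 6 without 1 array. The interferon, cytokine, ribosomal and oxidative phosphorylation calls at the higher dose held in 14 of 14 other alternatives each, cell cycle in 12 and glycolysis in 9, and the 2 downward lower-dose calls in 12 each. All of these alternatives used the preset correlation, so they share p-values that do not reflect the small number of arrays. With the span trend removed, 3 and 7 lists passed: at the lower dose cell cycle was gained (adjusted p = 0.0298) and endothelial markers lost (0.0799), and at the higher dose the stress response list was gained (0.0444). The correlation between the doses, 0.295, was 0.1 among probes above the median and 0.208 to 0.487 without 1 array (SD 0.108). Of 81 named values at the higher dose, 0 reversed in any alternative, counting only sign changes of values past the threshold in either fit. Values that did not pass could change sign, as Jun did (0.03, −0.08 on values as deposited and −0.16 with equal medians). Of 486 without 1 array, 252 kept their side of the threshold, 233 lost it and 1 gained it, and the block ended 55. Low signal limits probes near the floor, which had no detection flags here.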

Other observations

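The families in this part and the single probes were chosen after the values were seen. The tests of ciliated cell genes and of a second probe were written before their results were seen.

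Gene families were picked by symbol after the largest changes were known, so no test of a family is given, and the values describe these arrays at the higher dose against control. Of 9 complement genes, 5 were past the threshold, all higher, including C1qb (log2 change 2.62 ± 0.25, adjusted p = 0.0186) and C3 (1.14 ± 0.15, adjusted p = 0.0215). Apoc2 (2.27 ± 0.23, adjusted p = 0.0189) and Apoe (1.74 ± 0.19, adjusted p = 0.0199) rose beside Apoc1. Of 19 MS4A genes, Ms4a7, Ms4a6d (2.44 ± 0.19, adjusted p = 0.0167) and Ms4a6c (2.01 ± 0.16, adjusted p = 0.0168) rose and Ms4a4d fell (−1.62 ± 0.26, adjusted p = 0.0276). Mitochondrial ribosomal proteins had median changes of 0.86 for the large subunit (45 genes, 24 higher and 1 lower past the threshold) and 0.79 for the small subunit (24 genes, 10 higher and 0 lower). The median was 0.93 for LSM and Sm proteins (15 genes, 9 higher and 1 lower), 0.61 for 20S proteasome subunits (17 genes, 6 higher and 0 lower) and −0.04 for 19S proteasome subunits (20 genes, 0 higher and 2 lower, Psmd1 and Psmd2), whose median was 0.30 on values as deposited and 0.22 with equal medians.

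Among the families picked, 6 had medians of −0.22 or below. The median was −0.74 for SR splicing factors (10 genes, 0 higher and 5 lower), including Srsf7 (−1.42 ± 0.20, adjusted p = 0.0239) and Srsf3 (−1.14 ± 0.18, adjusted p = 0.0273), −0.46 for hnRNP proteins (17 genes, 0 higher and 4 lower) and −0.40 for DEAD and DEAH box helicases (51 genes, 3 higher and 8 lower). It was −0.44 for ubiquitin-specific proteases (48 genes, 1 higher and 3 lower), and −0.22 both for zinc finger genes named Zfp (325 genes, 7 higher and 25 lower) and for kinesins (37 genes, 1 higher and 4 lower). Of the rest, the median was 0.50 for apolipoproteins (12 genes, 3 higher and 0 lower), 0.26 for V-ATPase subunits (21 genes, 3 higher and 0 lower) and 0.19 for cathepsins (17 genes, 0 higher and 1 lower). It was 0.32 for MS4A genes, 1.14 for complement genes, and near 0 for keratins (0.08), olfactory receptors (0.03) and Mediator subunits (0.02), which with equal medians stood at −0.07, −0.02 and −0.16.

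In all, 3 probes read over 1000 units on one side and under 20 on the other, between the higher-dose arrays and the other 4. Tti1 read −6 and −8 units against 1279 to 1788, Eid1 −2 and 8 against 4872 to 5920, and Crot 1370 and 1131 against 6 to 18. Among 1002 genes with 2 probes above the median intensity, the higher-dose changes of the probes correlated across genes at r = 0.513, which does not count genes as replicates. Of 221 genes whose brighter probe was called, the second probe had the same sign in 180, was called in the same direction in 78 and in the opposite direction in 4.

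The Foxj1 probe was brighter on all 4 treated arrays, at 1568, 1606, 3769 and 2760 units against 81 and 69. RNA of ciliated cells in the treated cultures is one candidate source, and the tables argue against it. Of 25 measured ciliated cell genes, the median log2 change at the higher dose was −0.05, with 0 past the threshold upward and 1 downward. Its bootstrap 95% interval, −0.33 to 0.15, resamples genes and does not measure variation between arrays. The 3 most abundant over the 6 arrays, Ccdc40, Tppp3 and Dnaic1, stood at 288, 239 and 256 units in controls and 380, 258 and 222 units at the higher dose. A fault of the single probe cannot be told apart from a change of the transcript, because 1 probe is named Foxj1.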
